A study of Caenorhabditis elegans with 21 samples.

How the data were processed

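The series compares wild-type C. elegans (N2) with 6 mutant genotypes of the pathway that controls the hypoxia-inducible factor HIF-1, and its title presents it as a genetic study of a pathway that uses whole transcriptomes as phenotypes. The genotypes were egl-9(sa307), rhy-1(ok1402), vhl-1(ok161), hif-1(ia4), egl-9(sa307) hif-1(ia4) and egl-9(sa307);vhl-1(ok161), each with 3 libraries, which gave 21 libraries. According to the sample records, the worms were young adults without visible eggs, grown on NGM plates with OP50 bacteria, and each sample held 30 to 50 worms. Worms were lysed with proteinase K, total RNA was cleaned with a Zymo microprep kit, and libraries were made with the SmartSeq2 protocol, which does not mark the strand. The submitters' processing notes name bcl2fastq 1.8.4 and kallisto, and a kallisto version, a genome build, a transcript set and the fragment length settings are not given in the sources used here.

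The deposited tables held kallisto's estimated counts and scaled transcript abundances (TPM) for 32905 transcripts per library. The estimated counts are expected values, of which 66.6% lay within 1e-06 of a whole number. They were summed over the transcripts of each gene and then rounded, which gave 22037 genes, 5333 of them with several transcripts. The deposited scaled transcript abundances (TPM) were not used in any test. Transcripts were matched to genes of the reference annotation Ensembl 115 (WBcel235), which is not stated to be the build used by the submitters. Of the transcripts, 28369 matched by transcript name, 4229 matched by sequence name and 307 matched no gene, and the unmatched transcripts held 0.102 to 0.127% of the counts of a library. A set of 97 gene symbols was shared by several gene identifiers, and their 205 identifiers were kept as separate genes, so counts of near-identical copies are uncertain. No pair of libraries was identical.

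Genes were tested with edgeR's quasi-likelihood F-test (edgeR 4.0.16, R 4.3.3) on all 21 libraries in 1 fit with genotype as the only term, TMM size factors and edgeR's expression filter at a minimum count of 10, which kept 13043 genes. The common biological coefficient of variation was 0.15, with 14 residual degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 within its comparison. There were 11 pairwise comparisons and 2 interactions, each interaction being the change in the genotype with 2 mutated genes minus the sum of the changes in the genotypes with 1. All p-values measure only the spread between these samples, because the sample records give no batch and do not say whether the 3 libraries of a genotype came from separate cultures. Levels are counts scaled to library size after TMM (CPM), and changes are log2 fold changes with a standard error. That error is the size of the change divided by the square root of its F statistic. It restates the test and is not a separate measure of uncertainty, also for genes with few counts in a group.

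Gene lists were written from general knowledge of C. elegans before the data were examined, and 7 of their entries matched no gene name in the annotation. The 25 lists were the hif-1 pathway, known hif-1 targets, sulfide and cysteine metabolism, iron homeostasis, the TCA cycle, glycolysis, the respiratory chain with ATP synthase, cytosolic ribosomal proteins, the proteasome, heat shock genes with chaperones, detoxification enzymes, innate immunity effectors, the insulin pathway with daf-16 targets, lipid metabolism, cuticle collagens, collagen prolyl hydroxylation and folding, yolk proteins, oocyte and eggshell genes, sperm genes, zygotic embryo genes, L4 molt genes, neuronal genes, body wall and pharyngeal muscle genes, intestinal genes and male-enriched genes. Each list was tested against all other genes with camera (limma 3.58.1) with the correlation within the list estimated from the data, adjusted by Benjamini-Hochberg over the 25 lists of a comparison, for the 6 comparisons with N2 and the 2 interactions. Members called are counted by the test of all genes and, beside it, by the same p-values adjusted over the list alone. Per-library list levels are mean log2 CPM of the members, after 0.2 was added, relative to the mean of N2. Lists share genes, so their calls are not independent. Known hif-1 targets share egl-9 and rhy-1 with the hif-1 pathway, and cysl-2, sqrd-1 and cdo-1 with sulfide and cysteine metabolism. They share ftn-1, ftn-2 and smf-3 with iron homeostasis, and cysl-1 is in both the hif-1 pathway and sulfide and cysteine metabolism.

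Named genes followed a fixed rule. Against N2, the 8 raised and 8 lowered genes with a gene name and the largest change were taken among called genes with a mean of at least 10 CPM in the higher group and all 3 libraries of 1 group above all 3 of the other, a separation that chance gives to 10% of unchanged genes. The largest 2 in each direction were taken whatever their name, and up to 4 members with the smallest p were taken from each list described. Other pairwise comparisons and interactions gave the 4 largest in each direction, without the separation for interactions, and the response shared by genotypes gave 10 in each direction. The genes egl-9, hif-1, vhl-1, rhy-1 and cysl-1 were always named, and where fewer genes qualified all were named. Of the genes so chosen, those whose call was lost in some alternative and that are not described are nep-23, dod-22, ckb-2 and F44E5.5 in hif-1, hmit-1.1, dhs-26 and acdh-2 in egl-9 hif-1, and srlf-34, clec-60, grl-5, rol-1 and dao-4 in egl-9;vhl-1 against egl-9. For a gene with no count in a group, the fold change is a lower bound that takes 3 counts over the group as a floor and covers counting error only. For a gene with 1 to 3 counts in a group, the ratio is given with a 95% counting interval.

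A slope method compared genotypes with 2 mutated genes to those with 1. For each gene called in egl-9 and, for vhl-1, also in vhl-1, the deviation of the 2-gene genotype from the sum of the separate changes was regressed on that sum by orthogonal regression through the origin, with 1000 bootstrap draws for the 95% interval. Simulated data under each model gave 10 slopes for comparison. Simulated data with egl-9 hif-1 equal to N2 were added after the results were seen. The method was tried on data with known changes put in. Counts were simulated from the N2 means and the fitted spread, and 12269 genes passed the filter. Changes of 1.5-fold were called in 36 of 58 genes that carried them (62.1%), changes of 2-fold in 53 of 67 (79.1%) and changes of 4-fold in 74 of 75 (98.7%). Of 12045 unchanged genes 3 were called, which was 1.6% of the calls. A simulated interaction was called in 108 of 142 genes, and a list lowered by design gave a camera adjusted p = 4.61e-09, although 2 lists were called where 1 had been lowered. In 20 data sets simulated without any change, the number of genes shared by 4 genotypes was 0. Pairs of genotypes shared 0 calls there too, so this outcome was close to fixed in advance. With genes simulated as independent, it does not show how many shared calls come from variation among the N2 libraries.

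Apart from those simulated data, the choices above and the alternatives to them were fixed before the data were examined, and no alternative was added later. Alternatives were RLE size factors, no filter, a stricter filter of at least 5 CPM in at least 3 libraries, DESeq2 1.42.0, a fit of only the genotypes compared, replicate number as a block, transcripts tested 1 by 1, a call at an adjusted p below 0.10, camera with a preset correlation, and each library left out in turn. The submitters' own statistical test is not given in the sources used here, and raw reads were not analysed here.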

Results

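RNA was sequenced from whole young adult worms of 7 genotypes, with 3 libraries each. A library held between 7329864 (egl-9 replicate 2) and 10102598 (rhy-1 replicate 1) estimated counts, and between 15536 (egl-9 hif-1 replicate 1) and 16344 (rhy-1 replicate 2) genes had a count. The 10 genes with the most counts took 10.3 to 20.97% of a library. The first principal component held 43.4% of the variance and the next held 17.7%. Genotypes are written here as egl-9, rhy-1, vhl-1, hif-1, egl-9 hif-1 and egl-9;vhl-1. A changed gene is 1 called at an adjusted p below 0.05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with n = 3 libraries per genotype. Each change is a log2 fold change with a standard error derived from its test. Levels are counts scaled to library size (CPM).

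The mutated genes were examined first, as a check of the labels. EGL-9 is the prolyl hydroxylase that marks HIF-1, VHL-1 is the ubiquitin ligase part that recognises the mark, and RHY-1 acts upstream of EGL-9 through the cysteine synthase-like protein CYSL-1. The hif-1 transcript was at 115.2 ± 14.2 CPM in N2 (mean ± SD) and at 17.7 ± 4.0 and 13.7 ± 0.337 in hif-1 and egl-9 hif-1. The vhl-1 transcript is rare, with 17, 19 and 9 counts in the N2 libraries, and had 0 counts in all 6 libraries of vhl-1 and egl-9;vhl-1, which was at least 14.7-fold and at least 15.1-fold lower. The egl-9 transcript was not lost in egl-9 worms (94.2 ± 8.54 against 20.7 ± 1.57 in N2), nor was rhy-1 in rhy-1 worms (168 ± 9.49 against 37.2 ± 3.13). A count per gene does not show which part of a gene was read, so these 2 labels were not checked by it. The egl-9 transcript was at 109.4 ± 11.47 in egl-9;vhl-1, at 55.2 ± 5.29 in rhy-1, at 54.8 ± 5.99 in vhl-1, at 30.6 ± 1.32 in hif-1 and at 22 ± 0.755 in egl-9 hif-1.

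**Figure D1:**
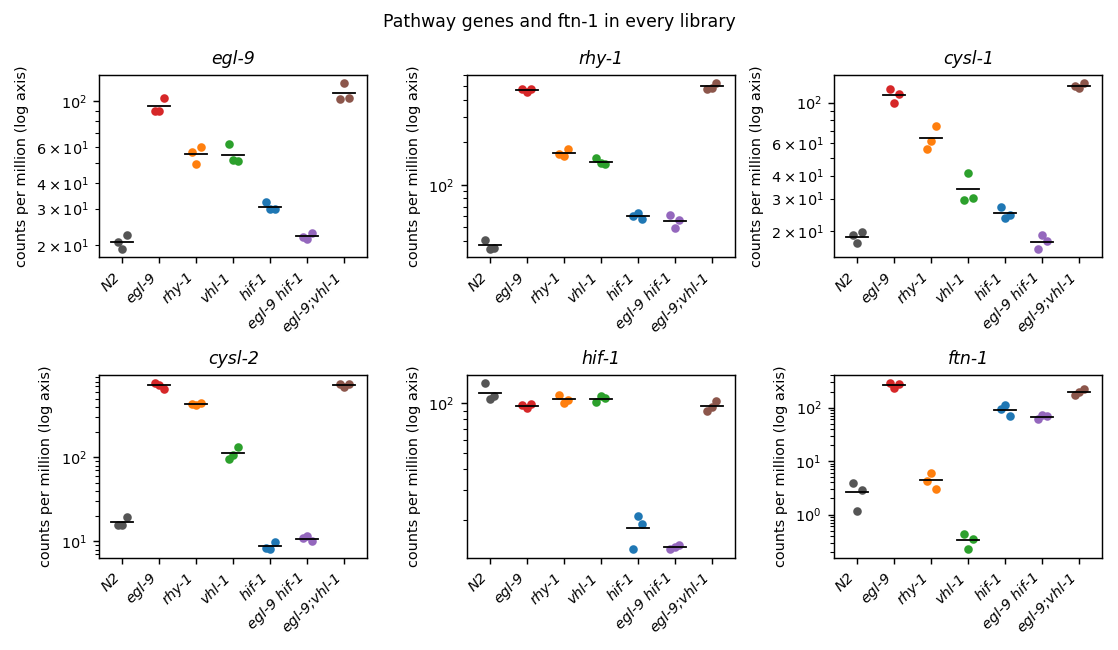
Level (CPM) of 6 genes of the pathway and its targets in every library, on a log axis, with a line at the mean of each genotype.

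In the WBcel235 assembly of the reference annotation used here, egl-9 lies on chromosome V at 10468517 to 10476915 and hif-1 on chromosome V at 20780407 to 20785260. The other mutated genes are vhl-1 on chromosome X at 11307356 to 11308518 and rhy-1 on chromosome II at 9161379 to 9163448. The gene cysl-1 lies on chromosome X at 9952579 to 9954533, cysl-2 on chromosome II at 14492874 to 14494451, ftn-1 on chromosome V at 7546468 to 7547579 and smf-3 on chromosome IV at 2618869 to 2625503. The gene haf-6 lies on chromosome I at 1162880 to 1175809, and nkat-3 on chromosome X at 15441731 to 15443630. All of them are protein coding.

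Loss of the HIF-1 hydroxylase was asked about by comparing egl-9 with N2. In egl-9, 3352 of 13043 tested genes changed, 1921 up and 1431 down, and 1462 of them at least 2-fold. The largest named rises were grl-16, a hedgehog-related gene of the epidermis, at 9.75 ± 2.23 (498 against 0.565 CPM). Next came the collagens col-156 (8.72 ± 1.48), col-49 (8.66 ± 2.15), dpy-13 (8.22 ± 2.03), col-175 (8.14 ± 1.97) and col-63 (7.80 ± 1.81), and lpr-6, a lipocalin-related gene (7.81 ± 0.27). The gene tag-297 had 3 counts in N2 and was 317-fold higher (95% counting interval 108.5 to 1538). T19C3.2 and T05B4.13 had no counts in N2 and were at least 147-fold higher. The largest named falls were pud-3 (−8.31 ± 0.69, 0.565 against 186 CPM), pud-4 (−6.58 ± 0.55) and pud-1.2 (−4.26 ± 0.61), whose names stand for proteins up-regulated in daf-2 mutants. The desaturase gene fat-7 (−4.99 ± 0.31) fell, as did dach-1, dhs-26, acdh-2 and fpn-1.2 (−4.71 ± 0.35, −4.63 ± 0.59, −3.99 ± 0.44 and −3.97 ± 0.35). Fits of only egl-9 and N2 called 2234 genes and left T19C3.2 uncalled (edgeR adjusted p = 0.0581), and transcripts tested 1 by 1 gave 2210.

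Of 14 measured known hif-1 targets, 12 rose and 2 fell in egl-9 (12 and 2 adjusted over the list alone), with a median of 3.27 (camera adjusted p = 1.47e-10). Among the rises were the nuclear receptor gene nhr-57 (5.98 ± 0.13, edgeR adjusted p = 3.24e-19), the cyanoalanine synthase gene cysl-2 (5.39 ± 0.13) and rhy-1 itself (3.65 ± 0.09). The list also holds the ferritin genes ftn-1 (6.61) and ftn-2 (1.31). Both also rose in egl-9;vhl-1 (6.19 and 1.32), and without hif-1, in hif-1 (5.06 and 1.13) and egl-9 hif-1 (4.65 and 1.08). A rise of these genes is therefore no sign of hif-1 activity, and counts up and down of this list mix both kinds of target. In the list of the hif-1 pathway, 10 genes measured, egl-9 (2.19 ± 0.10), cysl-1 (2.56 ± 0.12) and rhy-1 rose and none fell. The hif-1 transcript was not called (−0.26, edgeR adjusted p = 0.0782), but it was called without hif-1 replicate 1 (0.0216) or hif-1 replicate 2 (0.0443). The hif-1 pathway list was called (median 0.06, mean 0.79, camera adjusted p = 2.10e-04), but not without the filter (0.0545) or with only egl-9 and N2 fitted (0.0748). Its 3 called members are also in known hif-1 targets (egl-9 and rhy-1) or in sulfide and cysteine metabolism (cysl-1). The calls of these lists are therefore not separate results. In sulfide and cysteine metabolism, 9 of 19 rose and 2 fell (9 and 3 adjusted over the list alone), led by sqrd-1, a sulfide quinone oxidoreductase (7.56 ± 0.21), mpst-3 (4.64 ± 0.12) and ethe-1 (2.80 ± 0.11). The median of this list was −0.03 although its mean was 1.49 and the test pointed up (camera adjusted p = 2.65e-04).

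Innate immunity effectors rose in egl-9, 20 up and 4 down of 34 (20 and 5 adjusted over the list alone), with a median of 1.04 (camera adjusted p = 5.92e-04). The CUB-domain gene dod-24 led them (3.81 ± 0.11). Lipid metabolism fell, 3 up and 18 down of 36 (3 and 21 adjusted over the list alone), with a median of −0.34 (camera adjusted p = 0.0133). The fatty acid genes ech-6 and elo-6 were at −1.21 and −1.15. The insulin pathway with daf-16 targets rose, 7 up and none down of 16 (9 and 0 adjusted over the list alone), with a median of 0.42 (camera adjusted p = 0.0106). It was not called with only egl-9 and N2 fitted (0.0702). In glycolysis 10 genes rose and 3 fell of 19 (11 and 3 adjusted over the list alone, camera adjusted p = 0.216). The aldolase gene aldo-1 was at 1.2 ± 0.08 and the lactate dehydrogenase gene ldh-1 at 0.90 ± 0.07. Cuticle collagens had 93 up and 15 down of 133 (96 and 16 adjusted over the list alone) and a median of 3.35. Camera with the estimated correlation gave an adjusted p = 0.216, or 0.045 without vhl-1 replicate 2. The 27 L4 molt genes had a median of 3.39 (camera adjusted p = 0.216). Their level relative to N2 was 3.9, 2.47 and 2.26 in the egl-9 libraries, where the collagen level was 3.22, 2.63 and 3.13. The prolyl 4-hydroxylase genes dpy-18 (2.75 ± 0.18) and phy-2 (3.37 ± 0.23) rose. Their list, collagen hydroxylation and folding, had 3 up and 2 down of 11 (3 and 2 adjusted over the list alone, camera adjusted p = 0.308).

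**Figure D2:**
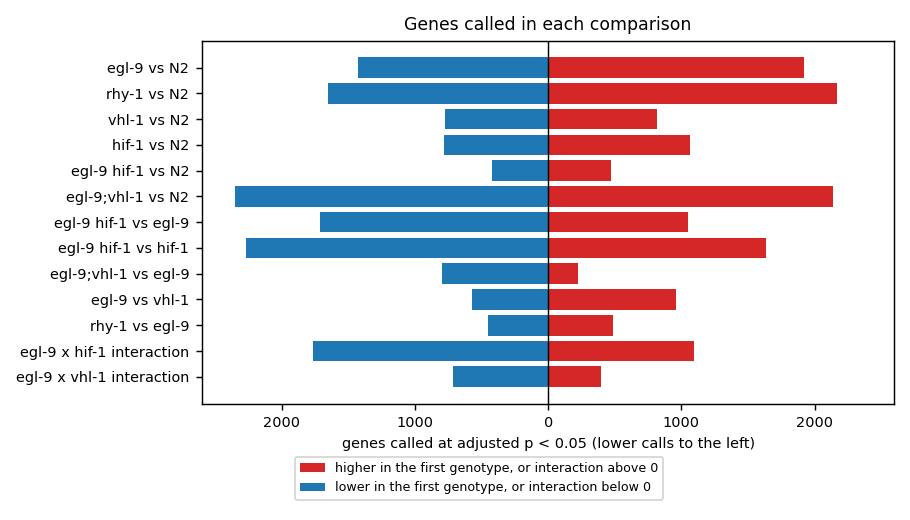
Number of genes called up and down in each of the 11 pairwise comparisons and the 2 interactions.

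Loss of rhy-1 was compared with N2 in the same way. In rhy-1, 3826 genes changed, 2169 up and 1657 down, and 1347 at least 2-fold. The largest rises were again grl-16 (8.65 ± 2.22), grl-5 (8.03 ± 1.90) and the cuticle genes sqt-1 (7.64 ± 2.02), dpy-13 (7.57 ± 2.01) and col-175 (7.43 ± 1.98). Few N2 counts set the base for phat-5 (365-fold, 65.5 to 14420, 1 count in N2) and dao-4 (239-fold, 66.1 to 1972, 2 counts in N2). T19C3.2 was at least 146-fold and T05B4.13 at least 106-fold higher. The falls were pud-3 (−6.03 ± 0.55), pud-4 (−5.98 ± 0.49), fat-7 (−4.83 ± 0.30), dhs-26 (−4.41 ± 0.56), and pud-1.2 (−3.48 ± 0.59). Further falls were drd-10 (−3.24 ± 0.53), the half-transporter gene haf-6 (−2.80 ± 0.13) and fat-5 (−2.73 ± 0.53). The rise of col-49 (7.76, edgeR adjusted p = 0.0163) was not called without N2 replicate 1 (0.0589), N2 replicate 2 (0.0639) or N2 replicate 3 (0.0524). The rise of sqt-1 was not called by transcripts (0.0931), and the fall of fat-5 not with only rhy-1 and N2 fitted (0.0529). Transcripts tested 1 by 1 gave 2518 calls.

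Known hif-1 targets rose in rhy-1, 10 up and none down of 14 (10 and 0 adjusted over the list alone), with a median of 1.79 (camera adjusted p = 5.47e-09). The genes nhr-57 and cysl-2 were at 5.53 ± 0.13 and 4.66 ± 0.12. Sulfide and cysteine metabolism had 11 up and 2 down of 19 (11 and 2 adjusted over the list alone), with a median of 1.18 (camera adjusted p = 1.24e-04) and sqrd-1 at 6.94 ± 0.20. The hif-1 pathway list was called up (camera adjusted p = 0.0154) although its median was −0.05. It was not called without the filter (0.151) or with only rhy-1 and N2 fitted (0.408). Lipid metabolism had 2 up and 17 down of 36 (3 and 18 adjusted over the list alone), with a median of −0.36 (camera adjusted p = 0.0304). This call was lost without hif-1 replicate 1 (0.0502) or with only rhy-1 and N2 fitted (0.182). Innate immunity effectors had 15 up and 3 down of 34 (15 and 3 adjusted over the list alone, camera adjusted p = 0.0659), with lys-7 at 2.70 ± 0.20. They were called without egl-9 replicate 3 (0.0296) or rhy-1 replicate 1 (0.0379), or with the stricter filter (0.0336). Cytosolic ribosomal proteins had 60 of 66 members down and none up (61 and 0 adjusted over the list alone), the respiratory chain 29 of 36 down and none up (30 and 1), and the proteasome 28 of 32 down and none up (31 and 0). Their medians were −0.52, −0.36 and −0.40, with camera adjusted p = 0.19, 0.157 and 0.23. The fall of ribosomal proteins was not particular to rhy-1. In egl-9 and egl-9 hif-1, 42 and 21 of the 66 were down and none up, each with a median of −0.30. Without N2 replicate 2 those numbers were 12 and 2. In vhl-1 8 were down and none up, and in hif-1 2 were up and 2 down. Cuticle collagens had 91 up and 9 down of 133 (97 and 12 adjusted over the list alone), with a median of 2.82 (camera adjusted p = 0.195). The L4 molt level relative to N2 was 3.61, 2.68 and 2.51 in the rhy-1 libraries.

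Loss of the ubiquitin ligase part was asked about with vhl-1 against N2. In vhl-1, 1591 genes changed, 819 up and 772 down, and 485 at least 2-fold. The methyltransferase gene comt-4 rose by 8.81 ± 0.51 (175 against 0.370 CPM), the flavin monooxygenase gene fmo-2 by 5.90 ± 0.61, and the lectin gene clec-210 by 5.68 ± 0.37. Further rises were 5.66 ± 0.61 for the glutathione S-transferase gene gst-19, 5.49 ± 0.13 for the methyltransferase gene rips-1, 5.4 ± 0.51 for dod-3, 5.02 ± 0.19 for sqrd-1 and 4.89 ± 0.39 for the protease gene asp-12. F15E11.10 had no counts in N2 and was at least 197-fold higher. The kynurenine aminotransferase gene nkat-3 had 1 count over the vhl-1 libraries and was 714-fold lower (128 to 28190). The other falls were pud-3 (−6.38 ± 0.57), pud-4 (−5.83 ± 0.49), fat-5 (−5.11 ± 0.72), fat-7 (−4.98 ± 0.31), dhs-26 (−4.66 ± 0.58), pgph-3 (−2.82 ± 0.55) and gba-4 (−2.69 ± 0.42). The number of calls was 965 without N2 replicate 2, 940 without vhl-1 replicate 1 and 1057 without vhl-1 replicate 2. It was 1014 with only vhl-1 and N2 fitted and 790 by transcripts.

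Known hif-1 targets rose in vhl-1, 9 up and 2 down of 14 (10 and 3 adjusted over the list alone), with a median of 1.78 (camera adjusted p = 1.81e-08). Among them cysl-2 was at 2.71 ± 0.12, nhr-57 at 2.81 ± 0.13 and rhy-1 at 145 ± 8.13 CPM. The 2 that fell were the ferritin genes ftn-1 (−2.96) and ftn-2 (−0.69). Innate immunity effectors had 16 up and 5 down of 34 (17 and 6 adjusted over the list alone), with a median of 0.34 (camera adjusted p = 0.00833). Lipid metabolism had 3 up and 12 down of 36 (3 and 16 adjusted over the list alone), with a median of −0.43 (camera adjusted p = 0.0181, or 0.148 with only vhl-1 and N2 fitted). Sulfide and cysteine metabolism was called up with 7 up and 1 down of 19 (7 and 2 adjusted over the list alone, camera adjusted p = 0.00349) at a median of −0.11 and a mean of 0.83. It was not called without the filter (0.0892) or with only vhl-1 and N2 fitted (0.148). The hif-1 pathway list was called up (median 0.05, camera adjusted p = 0.00997) at a mean of −0.29, which the lost vhl-1 transcript pulled down. This call was lost without the filter (0.158) or with only vhl-1 and N2 fitted (0.148). Cuticle collagens had a median of 0.90 (camera adjusted p = 0.457) with levels of 0.6, 2.17 and −0.13 in the 3 vhl-1 libraries. The L4 molt levels there were 0.75, 1.33 and −0.28.

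Genes that changed in opposite directions in egl-9 and vhl-1 numbered 29, with 19 without N2 replicate 2, 48 at an adjusted p below 0.10 and 16 by transcripts. The iron importer gene smf-3 had no counts in egl-9, at least 15.8-fold below N2, and rose by 4.35 ± 0.34 in vhl-1 (40.4 ± 9.32 CPM). The ferritin gene ftn-1 rose by 6.61 ± 0.29 in egl-9 (266 ± 28.4 against 2.67 ± 1.39 CPM) and fell by 2.96 ± 0.59 in vhl-1 (0.336 ± 0.107). The others with the largest differences were T20D4.3 (−3.0 and 2.72), ugt-14 (2.13 and −2.31), asp-8 (−3.38 and 0.94), nlp-31 (1.85 and −2.06), C17B7.5 (−2.65 and 0.99), txt-11 (−2.04 and 1.52), F18E3.12 (1.5 and −1.94) and the lysozyme gene lys-7 (2.35 and −1.02). In vhl-1 txt-11 was not called without N2 replicate 2 (0.056), and C17B7.5 was not called in 11 of 21 fits with 1 library left out. Compared directly, 1527 genes differed between egl-9 and vhl-1, 958 higher and 569 lower in egl-9. Higher were ftn-1 at 9.57 ± 0.37, nkat-3 584-fold higher (105 to 23060, 1 count in vhl-1), the fatty acid binding gene far-3 at 7.29 ± 0.36 and col-156 at 6.65 ± 1.21. Lower were smf-3 (at least 325-fold), comt-4 at −5.15 ± 0.37, asp-8 at −4.32 ± 0.20 and fpn-1.2 at −4.13 ± 0.34. Only the 2 genotypes fitted gave 742 calls and transcripts gave 799.

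Loss of the transcription factor itself was asked about with hif-1 against N2. In hif-1, 1847 genes changed, 1066 up and 781 down, and 371 at least 2-fold. The ferritin gene ftn-1 rose by 5.06 ± 0.28 (91.0 ± 20.9 CPM), followed by T08B6.9 (2.76 ± 0.38). Next were the lipase gene lipl-1 (2.64 ± 0.50), the heme-responsive gene hrg-9 (2.44 ± 0.18), cyp-13A12 (2.38 ± 0.34) saeg-2 (2.2 ± 0.23) and osg-1 (1.91). Besides hif-1 (−2.71 ± 0.12), the falls included pgph-3 (−2.71 ± 0.55), haf-6 (−2.67 ± 0.13), fig-1 (−2.14 ± 0.25), acdh-2 (−2.0 ± 0.36) and hacd-1 (−1.46 ± 0.20). Innate immunity effectors rose, 17 up and 4 down of 34 (17 and 4 adjusted over the list alone), with a median of 0.82, or 0.74 with 2 members at their bound (camera adjusted p = 0.00769). The lysozyme gene lys-2 was at 1.64 ± 0.11. Known hif-1 targets had 5 up and 3 down of 14 (5 and 5 adjusted over the list alone, camera adjusted p = 0.0622). Among them sqrd-1 was at −1.67, cysl-2 at −0.96 ± 0.13 and rhy-1 at 0.69 ± 0.09. The 5 that rose include the ferritin genes ftn-1 and ftn-2 (1.13). Iron homeostasis was called (camera adjusted p = 0.0499) but in 13 of 21 fits with 1 library left out it was not (0.0505 to 0.161). It was also not called with RLE size factors (0.067), without the filter (0.257), with the replicate number as a block (0.11) or with only hif-1 and N2 fitted (0.269). Detoxification enzymes were not called (camera adjusted p = 0.0936). The number of calls was 1097 without N2 replicate 1, 835 without N2 replicate 2, 1060 without hif-1 replicate 2, and 846 without hif-1 replicate 3. It was 1104 with only hif-1 and N2 fitted, 591 by transcripts and 2906 at an adjusted p below 0.10. By transcripts acdh-2 (0.335) and sqrd-1 (0.175) were not called.

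The genotype egl-9 hif-1 asked whether the changes in egl-9 need hif-1. Against N2, 894 genes changed in egl-9 hif-1, 472 up and 422 down, and 129 at least 2-fold. The rises were ftn-1 (4.65 ± 0.28), parg-2 (3.84 ± 0.52), the ammonium transporter gene amt-1 (2.17 ± 0.38), cyp-14A5 (2.0 ± 0.21), the asparagine synthetase gene asns-2 (1.99 ± 0.20), fat-5 (1.86) and ugt-32 (1.46 ± 0.24). The falls were hif-1 (−3.07 ± 0.12), adh-1 (−2.65 ± 0.32), haf-6 (−2.63 ± 0.13), the pterin synthesis gene cat-4 (−1.84 ± 0.13), asp-8 (−1.77 ± 0.17) and fpn-1.2 (−1.56 ± 0.27). None of the 25 lists was called in this comparison, and known hif-1 targets had 3 up and 4 down of 14 (3 and 5 adjusted over the list alone) at a median of −0.39 (camera adjusted p = 0.989). By transcripts amt-1 (0.117), fat-5 (0.104) and fpn-1.2 (0.0623) were not called, nor was fat-5 with only egl-9 hif-1 and N2 fitted (0.135). The number of calls was 393 without N2 replicate 2, 573 without N2 replicate 3, and 354 without egl-9 hif-1 replicate 3. It was 283 with only the 2 genotypes fitted, 413 by transcripts and 1368 at an adjusted p below 0.10.

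Of the 3352 genes changed in egl-9, 2050 (61.2%) were called back toward N2 when egl-9 hif-1 was compared with egl-9, 1326 of the 1921 raised and 724 of the 1431 lowered. There were 469 (14%) still called in the same direction in egl-9 hif-1, and 56 were called in the opposite direction. These numbers were 194 and 37 without N2 replicate 2, 297 and 40 without N2 replicate 3, 211 and 34 without egl-9 hif-1 replicate 3, and 143 and 26 with only the genotypes compared in the fit. They were 173 and 28 by transcripts, and 747 and 90 at an adjusted p below 0.10. The median ratio of the change in egl-9 hif-1 to that in egl-9 was 0.20 (95% bootstrap interval over genes 0.18 to 0.21), with 0.14 to 0.291 over fits without 1 library. In 10 data sets simulated with egl-9 hif-1 equal to N2 it was 0.02 to 0.03. These simulations treat genes as independent, so variation that many genes share between the N2 libraries is not covered. The comparison of egl-9 hif-1 with egl-9 called 2766 genes, 1053 up and 1713 down. The genes amt-1 (459-fold up, 82.5 to 18150, 1 count in egl-9), pud-3 (8.44 ± 0.69), pud-4 (6.47 ± 0.55) and fat-7 (5.45 ± 0.31) rose. The collagen genes col-73 (3541-fold down, 636 to 139800) and col-88 (2439-fold down, 438 to 96340), fell to 1 count each in egl-9 hif-1, and abu-6 (at least 256-fold) and fmo-2 (at least 157-fold) fell to none. With only the genotypes compared in the fit, 1118 genes were called back and abu-6 was not called (0.121), and by transcripts 1365 were called back.

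**Figure D3:**
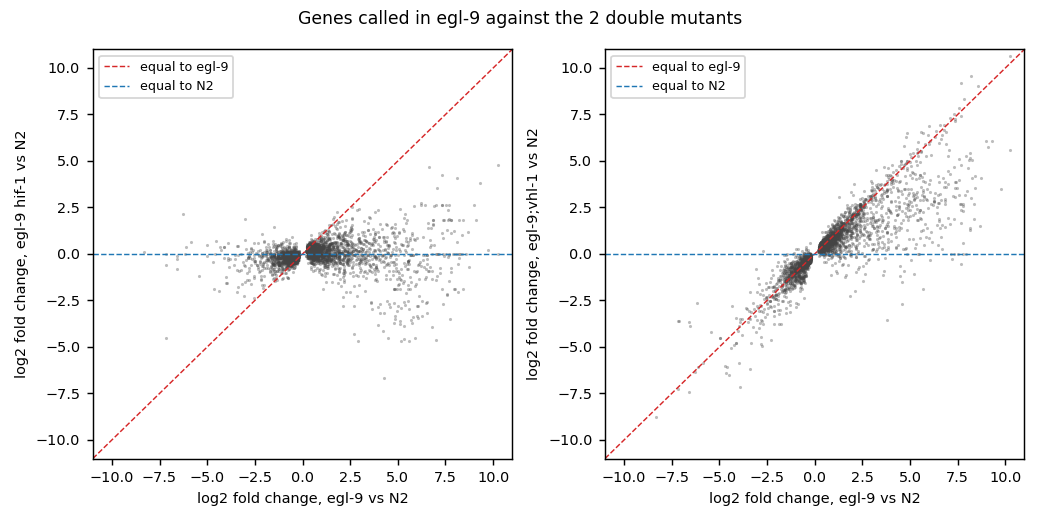
Change of each gene called in egl-9 against its change in egl-9 hif-1 and in egl-9;vhl-1, all relative to N2, with dashed lines where the genotype equals egl-9 and where it equals N2.

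The interaction of egl-9 and hif-1 was called in 2865 genes, 1098 up and 1767 down. Known hif-1 targets had 1 up and 12 down of 14 (2 and 12 adjusted over the list alone, camera adjusted p = 7.38e-10). Among them nhr-57 was at −6.49 ± 0.21, rhy-1 at −3.77 ± 0.12 and cysl-2 at −5.09 ± 0.18. Innate immunity effectors had 3 up and 21 down of 34 (3 and 22 adjusted over the list alone), with a median of −1.44 (camera adjusted p = 1.09e-04), with dod-24 at −5.41. Sulfide and cysteine metabolism (1 up and 8 down of 19, 2 and 8 adjusted over the list alone) and the hif-1 pathway each had a camera adjusted p = 7.10e-04, the latter 0.131 without the filter. The largest named were the heat shock genes hsp-16.41 (9.90 ± 2.08), hsp-16.2 (8.36 ± 1.87) and hsp-70 (8.18 ± 2.00). For the 16 heat shock genes and chaperones the N2 libraries stood apart, at −1.87, 0.76 and 1.11 around their mean, and the camera adjusted p of the list was 0.194, or 0.0389 without N2 replicate 1, the low one. In the other direction were grl-16 (−15.79 ± 3.12), col-156 (−14.63 ± 2.28) and col-175 (−14.45 ± 3.30). The interaction was also called for amt-1 (up) and col-73 (down), with no size given because amt-1 had 1 count in egl-9 and col-73 had 1 in egl-9 hif-1. Without hif-1 replicate 1 col-73 (0.141) and col-175 (0.197) were not called. The slope of the deviation from additivity was −1.02 (95% bootstrap interval over genes −1.04 to −0.99, 3352 genes). Simulated data gave −0.09 for additive changes and −0.92 (−0.94 to −0.91) for a genotype equal to hif-1. The observed slope lay outside both. A genotype equal to N2 deviates by minus the whole sum by definition, so the slope cannot tell equality with hif-1 from equality with N2.

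The comparison of egl-9 hif-1 with hif-1 asked what egl-9 loss does without hif-1. It called 3902 genes, 1634 up and 2268 down, more than egl-9 hif-1 against N2, and 892 of them at least 2-fold. The heat shock genes hsp-70 (6.52 ± 1.66), hsp-16.41 (5.97 ± 1.56) and hsp-16.2 (5.43 ± 1.47) and pgph-3 (3.76 ± 0.55) were higher. The gene hsp-70 had only 12, 4 and 2 counts in the hif-1 libraries. In egl-9 hif-1 it was at 64.5 ± 8.91 CPM, within the N2 range of 1.964 to 138.5. The higher level against hif-1 need therefore not come from egl-9 loss. The largest falls were the collagens col-156 (−5.92), col-120 (−4.84), col-161 (−4.82) and col-157 (−4.09). Each of these calls was lost without hif-1 replicate 1 (0.12, 0.111, 0.0891 and 0.156) and without any 1 of the egl-9 hif-1 libraries (0.0589 to 0.11). Lost too were those of col-120, col-161 and col-157 without hif-1 replicate 3 (0.0686, 0.0808 and 0.0517). Transcripts tested 1 by 1 gave 2312 calls.

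The genotype egl-9;vhl-1 asked what vhl-1 loss adds to egl-9 loss. Against N2, 4492 genes changed, 2139 up and 2353 down, and 1908 at least 2-fold. Of the genes changed in egl-9, 2398 (71.5%) were called in the same direction. The rises were the lectin gene clec-60 (at least 91.3-fold), T05B4.13 (at least 194-fold), lpr-6 (8.33 ± 0.26), sqrd-1 (7.87 ± 0.21), and nspe-4 (7.41 ± 0.22). Others were col-78 (180-fold, 49.8 to 1486, 2 counts in N2), gst-19 (6.96 ± 0.64), rips-1 (6.65 ± 0.14) and far-3 (6.60 ± 0.35). The falls were nkat-3 (731-fold, 131 to 28870, 1 count), pud-3 (−8.76 ± 0.71), pud-4 (−7.44 ± 0.59), and dhs-26 (−6.38 ± 0.69). Further falls were dach-1 (−6.03 ± 0.40), fpn-1.2 (−5.85 ± 0.42), cyp-35A3 (−4.97 ± 0.33) and pud-1.2 (−4.88 ± 0.63). Known hif-1 targets had 12 up and 1 down of 14 (12 and 1 adjusted over the list alone), with a median of 3.17 (camera adjusted p = 2.56e-10). Innate immunity effectors had 21 up and 4 down of 34 (21 and 4 adjusted over the list alone), with a median of 0.90 (camera adjusted p = 0.00167). Sulfide and cysteine metabolism was called (9 up and 6 down of 19, 9 and 8 adjusted over the list alone, camera adjusted p = 6.24e-04), as were the hif-1 pathway (3.43e-04) and the insulin pathway (0.0264). Without the filter the first 2 were not called (0.0862 and 0.0862), nor was the insulin pathway with only the 2 genotypes fitted (0.12). Glycolysis had 13 up and 3 down of 19 (14 and 4 adjusted over the list alone), with a median of 0.50 (camera adjusted p = 0.0578). It was called without rhy-1 replicate 3 (0.0381), egl-9 hif-1 replicate 1 (0.0398) or egl-9 hif-1 replicate 3 (0.039).

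Sperm genes fell in egl-9;vhl-1, 40 of 44 down and none up (40 and 0 adjusted over the list alone), with a median of −1.13 (camera adjusted p = 0.31). Among them were the major sperm protein genes msp-64 (−1.41 ± 0.20), msp-56 (−1.23) and msp-32 (−1.29). Oocyte and eggshell genes had 17 up and 1 down of 28 (19 and 3 adjusted over the list alone), with a median of 0.30 (camera adjusted p = 0.567). The eggshell gene cpg-3 was at 1.01 ± 0.09. Cytosolic ribosomal proteins had 56 of 66 members down and none up (59 and 0 adjusted over the list alone, camera adjusted p = 0.479). Cuticle collagens had 52 up and 14 down of 133 (55 and 14 adjusted over the list alone), with a median of 1.49, or 1.41 with absent members at their bound (camera adjusted p = 0.567). The libraries had collagen levels of 1.06, 1.49 and 1.43 and L4 molt levels of 0.45, 1.33 and 1.17 relative to N2.

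**Figure D4:**
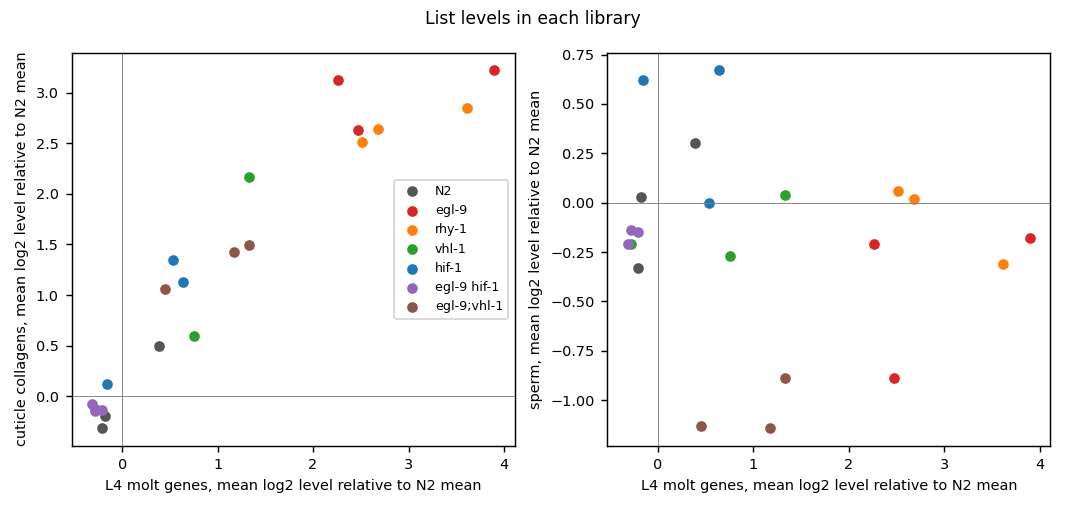
Level of L4 molt genes in each library against the level of cuticle collagens and of sperm genes, relative to the N2 mean.

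Compared directly with egl-9, egl-9;vhl-1 differed in 1027 genes, 227 up and 800 down. The gene nkat-3 was 598-fold lower (107 to 23610, 1 count in egl-9;vhl-1), and cls-3, a microtubule-binding gene, and dyf-3, a cilium gene, were higher (1.62 ± 0.23 and 1.68 ± 0.24). The number of calls was 222 without egl-9 replicate 1, 1789 without egl-9 replicate 2, 403 without egl-9 replicate 3, and 254, 635 and 371 without replicates 1, 2 and 3 of egl-9;vhl-1. It was 522 with only the 2 genotypes fitted, 229 by transcripts, where dyf-3 was not called (0.303), and 1698 at an adjusted p below 0.10.

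The interaction of egl-9 and vhl-1 was called in 1111 genes, 395 up and 716 down, with 645 without vhl-1 replicate 2, 722 with only the genotypes involved fitted and 495 by transcripts. Known hif-1 targets had 3 up and 8 down of 14 (3 and 8 adjusted over the list alone, camera adjusted p = 1.45e-06), with sqrd-1 at −4.71 ± 0.24 and nhr-57 at −2.87. The rise in egl-9;vhl-1 was less than the sum of the rises in egl-9 and vhl-1. Innate immunity effectors (2 up and 11 down of 34, 3 and 13 adjusted over the list alone, camera adjusted p = 0.00858), sulfide and cysteine metabolism (0.00567) and lipid metabolism (0.00303, median 0.48) were also called. The interaction was positive for fat-7 (5.44 ± 0.48), the glucuronosyltransferase gene ugt-14 (2.73 ± 0.63) and the antimicrobial peptide gene nlp-31 (2.72 ± 0.51). The genes fat-7 and fat-5 fell in egl-9;vhl-1 (−4.53 and −3.55), by less than the sum of their falls in egl-9 (−4.99 and −3.02) and vhl-1 (−4.98 and −5.11). The positive call of fat-5 (4.57 ± 1.21) was lost without N2 replicate 2 (0.0515), egl-9 replicate 1 (0.0605) or 3 (0.0611), vhl-1 replicate 1 (0.0676) or 2 (0.0787), or egl-9;vhl-1 replicate 1 (0.0561), 2 (0.0607) or 3 (0.1). Without vhl-1 replicate 2, the calls of col-63 (−13.90, 0.0585), grl-5 (−13.88, 0.405), col-49 (−13.83, 0.717) and dao-4 (down, 2 counts in N2, 0.989) were lost. The slope of the deviation was −0.51 (95% bootstrap interval over genes −0.55 to −0.47, 1174 genes). Data simulated for it gave −0.05 (−0.06 to −0.04) for additive changes and −0.45 (−0.46 to −0.43) for a genotype equal to egl-9.

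The comparison of rhy-1 with egl-9 asked where these 2 genotypes part. It called 935 genes, 484 up and 451 down, with 612 without rhy-1 replicate 1, 520 with only the 2 genotypes fitted and 395 by transcripts. The lysozyme gene lys-10 (3.93 ± 0.43), the cystathionine gamma-lyase gene cth-1 (2.92 ± 0.31) and thn-2 (2.90 ± 0.36) were higher in rhy-1. The ferritin gene ftn-1 (−5.89 ± 0.27, 4.44 ± 1.48 CPM in rhy-1), asp-12 (−4.17 ± 0.36), drd-50 (−3.78 ± 0.29) and irg-5 (−3.15 ± 0.20) were lower. The gene pgph-3 was higher too (2.49 ± 0.47), but not with only the 2 genotypes fitted (0.136).

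A response shared by egl-9, rhy-1, vhl-1 and egl-9;vhl-1 held 850 genes called in the same direction in all 4, 429 up and 421 down. Independent lists of these sizes would share 3.29 and 1.94, but they take no account of the shared N2 libraries. Of the 429, 104 were also called up in egl-9 hif-1 and 103 in hif-1. Of the 421, 116 and 65 were called down there. In hif-1, 22 and 41 were called in the opposite direction. When egl-9 hif-1 was compared with egl-9, 301 of the 429 and 243 of the 421 were called back. Of the 10 rises named by their fitted mean over the 4, sqrd-1 (6.85), lpr-6 (6.64), nspe-4 (6.40), gst-19 (6.39), rips-1 (6.38), fmo-2 (5.56) and ech-9 (5.48) had more than 3 counts in N2. The other 3 had too few to be ranked. With no count in N2, clec-60 was at least 35.3-fold higher in egl-9, 16.19-fold in rhy-1, 34.25-fold in vhl-1 and 91.3-fold in egl-9;vhl-1. The ratio for col-78 (2 counts in N2) ran from 23.9 (6.615 to 197.3) in vhl-1 to 193 (53.4 to 1593) in egl-9, and that for ugt-18 (3 counts) from 11.13 (3.807 to 53.95) in rhy-1 to 98.0 (33.5 to 475) in egl-9;vhl-1. The 10 largest falls were pud-3 (−7.37), pud-4 (−6.46), dhs-26 (−5.02), fat-7 (−4.83), dach-1 (−3.71), pud-1.2 (−3.66), fat-5 (−3.60), acdh-2 (−2.89), cyp-35A5 (−2.72) and cyp-25A1 (−2.58). The desaturase gene fat-7 was at 139 ± 41.4 CPM in N2, 4.39 ± 1.18 in egl-9, 4.41 ± 0.131 in vhl-1 and 192 ± 41.6 in egl-9 hif-1. Within rhy-1 ech-9 was not called without any 1 of the N2 libraries (0.059, 0.108 and 0.0846), rhy-1 replicate 1 (0.0705) or rhy-1 replicate 3 (0.0889), and ugt-18 was not called without N2 replicate 1 (0.0863), N2 replicate 2 (0.0801) or rhy-1 replicate 1 (0.0518). Within vhl-1 pud-1.2 was not called without N2 replicate 1 (0.0502), 2 (0.0569) or 3 (0.0649) or vhl-1 replicate 1 (0.0889). The number shared was 510 without N2 replicate 2, 540 without vhl-1 replicate 1, 514 with only the genotypes compared in each fit and 428 by transcripts.

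Over all tested genes, changes correlated between egl-9 and rhy-1 (Pearson r 0.89, Spearman 0.71), egl-9 and egl-9;vhl-1 (0.78 and 0.78) and egl-9 and vhl-1 (0.70 and 0.65). For egl-9 and hif-1 they were 0.37 and 0.12, and for egl-9 and egl-9 hif-1 0.09 and 0.37. All share the 3 N2 libraries, which cannot be divided in 2 equal sets, so part of each correlation comes from them. Data simulated without change gave a Pearson r of 0.50 for egl-9 and rhy-1 and 0.49 for each of the other pairs. Changes that differ between genotypes lower r, so covariances were compared too. The covariance was 1.173 for egl-9 and rhy-1 against 0.044 in the simulated data, 0.28 for egl-9 and hif-1 against 0.043, and 0.056 for egl-9 and egl-9 hif-1 against 0.043. Genes raised in both egl-9 and rhy-1 numbered 1442, where independent lists would share 319.5, and genes lowered in both numbered 939 against 181.8. For egl-9 and egl-9 hif-1 these numbers were 252 against 69.5 and 217 against 46.3. Independent lists take no account of the shared N2 libraries, so an excess over them is not by itself a shared response.

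**Figure D5:**
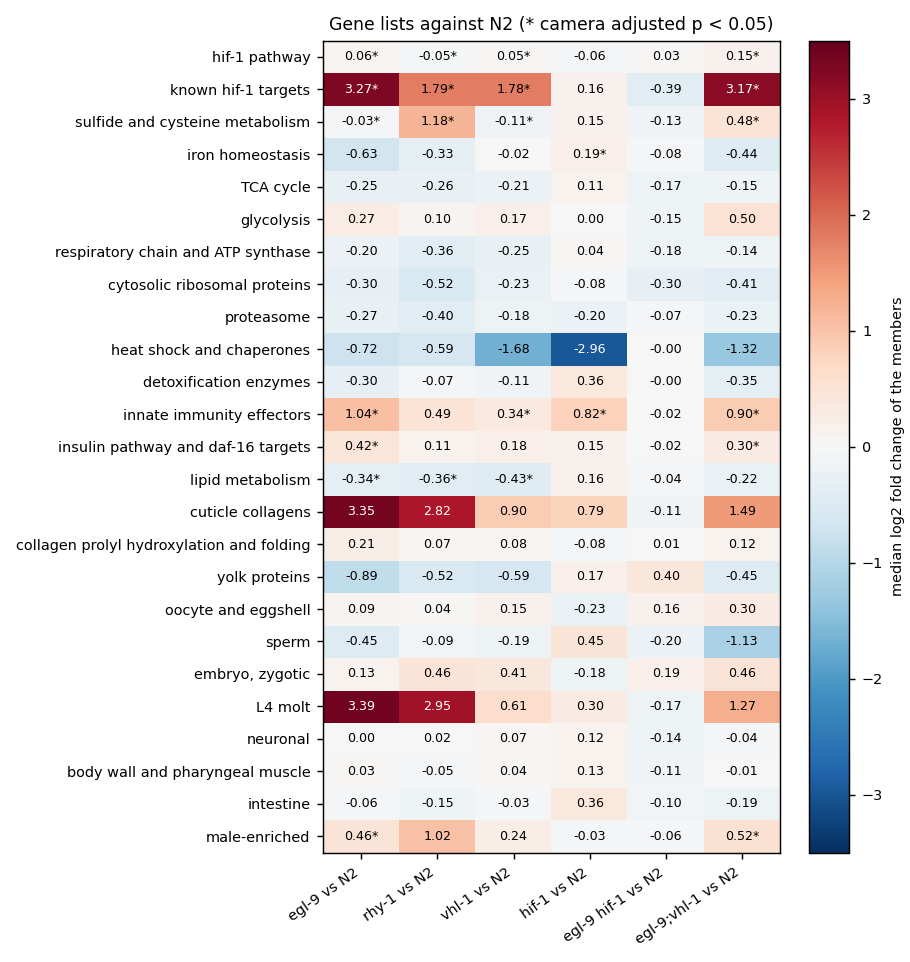
Median log2 fold change of each of the 25 gene lists in the 6 comparisons with N2, with a star where camera called the list.

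Among the other lists, the male-enriched list of 4 genes was called in egl-9 (camera adjusted p = 0.0382) and egl-9;vhl-1 (0.0264), in each by 1 called member, the protease inhibitor gene swm-1 (1.93 ± 0.10 in egl-9). In egl-9 it was not called without the filter (0.189) or with the replicate number as a block (0.0554). Nor was it called there without N2 replicate 1 (0.055), N2 replicate 3 (0.0604), egl-9 replicate 1 (0.0788), egl-9 replicate 2 (0.0569) or vhl-1 replicate 3 (0.0521). In egl-9;vhl-1 it was not called without the filter (0.0887). In the 6 comparisons with N2 the TCA cycle list had camera adjusted p-values of 0.19 to 0.848, yolk proteins 0.216 to 0.87, intestinal genes 0.212 to 0.7, detoxification enzymes 0.0936 to 0.989, and neuronal genes 0.527 to 0.929. In egl-9 the yolk protein gene vit-1 was at −1.76 ± 0.22 and the TCA cycle had 4 up and 11 down of 24 (4 and 13 adjusted over the list alone). With a preset correlation of 0.01 in camera every list called above was called again, and 81 further tests of the 200 were called, among them the cuticle collagens in egl-9 and rhy-1.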

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

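The tests of other splits of the libraries for the first 9 pairwise comparisons, of collagens in egl-9 hif-1, and of the position of haf-6 were chosen only after the results were seen, and the others before.

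The interaction of egl-9 and hif-1 was called in 2865 genes, and 4 of 25 lists were called in it by camera with adjusted p-values of 7.10e-04 for the hif-1 pathway, 7.38e-10 for known hif-1 targets, 7.10e-04 for sulfide and cysteine metabolism and 1.09e-04 for innate immunity effectors. Among the called genes with a gene name and a mean of at least 10 CPM in a genotype of the comparison, the largest fitted log2 differences were 9.90 for hsp-16.41, 8.36 for hsp-16.2, 8.18 for hsp-70, 7.71 for amt-1, −15.79 for grl-16, −15.40 for col-73, −14.63 for col-156 and −14.45 for col-175. Those of amt-1 and col-73 each rest on a group with 1 count and are no measure of size. The heat shock genes differed widely between the N2 libraries, with levels of −1.87, 0.76 and 1.11 around their mean. Of 40 draws that regrouped the libraries, 1, the real grouping, gave as many calls, and the highest other gave 1885. Such regroupings place differences between genotypes on the contrast, so their counts do not show what chance alone would give, and the draws say nothing on chance.

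The interaction of egl-9 and vhl-1 was called in 1111 genes. Camera called the hif-1 pathway (adjusted p = 0.0424), known hif-1 targets (1.45e-06), sulfide and cysteine metabolism (0.00567), innate immunity effectors (0.00858) and lipid metabolism (0.00303). The call of the hif-1 pathway was lost in 14 of 21 fits that left out 1 library (highest at 0.134, without N2 replicate 3). It was also lost without the filter on low counts (0.124), with the replicate number as a block (0.0727) and with only the genotypes compared in the fit (0.116). By the same choice the largest fitted log2 differences were 5.44 for fat-7, 4.57 for fat-5, 2.73 for ugt-14, 2.72 for nlp-31, −13.90 for col-63, −13.88 for grl-5, −13.83 for col-49 and −13.76 for dao-4, the last with 2 counts in N2 and so no measure of size. Of 40 draws 2 gave as many calls, the real grouping included, and the other gave 1671. These draws also place differences between genotypes on the contrast, so here too they say nothing on chance.

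For the 11 pairwise comparisons, 10 splits of the 6 libraries cannot give a share under 0.05. In each of them 1 of the 10 splits, the real one, gave as many calls as the real one. Every other split puts libraries of both genotypes in each group, so the difference between genotypes becomes spread within groups. Few calls there follow by construction, and the splits say nothing on chance. The highest number of calls in another split was 3 for egl-9 against N2 (3352 in the real one), 3 for rhy-1 (3826), 1 for vhl-1 (1591), 0 for hif-1 (1847), 0 for egl-9 hif-1 (894) and 0 for egl-9;vhl-1 (4492). It was 1 for egl-9 hif-1 against egl-9 (2766), 0 for egl-9 hif-1 against hif-1 (3902), 1 for egl-9;vhl-1 against egl-9 (1027), 15 for egl-9 against vhl-1 (1527) and 11 for rhy-1 against egl-9 (935).

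The rise of cuticle collagens in egl-9 was weighed against 3 explanations. Collagens are made in waves at each molt, so worms at an earlier stage would raise collagens and molt genes together. Within genotypes, the slope of each of 133 collagens on the level of 27 L4 molt genes correlated with its log2 fold change in egl-9 (r 0.84). The 95% interval of 0.78 to 0.90 is a bootstrap that treats collagens as independent. A positive correlation was the outcome written in advance for a difference in stage. A collagen with a wide range would have a large slope and a large change whatever raised it, so r cannot tell a difference in stage from another cause. A single outlying library was excluded, as 83 collagens were called up in the lowest case, without N2 replicate 2, against 93 with all libraries. In egl-9 hif-1 the collagen median was −0.11 against 3.35 in egl-9, so the rise was absent where hif-1 was lost too. In the interaction of egl-9 and hif-1 the collagens were not called by camera (adjusted p = 0.116), but they were without vhl-1 replicate 2 (0.025) or with only the genotypes compared in the fit (0.0233). A need for hif-1, direct or through the timing of the molt, and egl-9 hif-1 worms harvested at the stage of N2 would each give such medians, and the choice between them was left open.

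The loss of nkat-3 from both genotypes with vhl-1(ok161), and the fall of haf-6 in rhy-1, hif-1 and egl-9 hif-1, were weighed against variants carried by the strains. Genes changed at least 4-fold in vhl-1 were 6 beside 1014 others within 5 Mb of vhl-1, and 179 beside 11773 others elsewhere (odds ratio 0.39, 0.17 to 0.88, Fisher exact p = 0.0181). The outcome written in advance against a linked variant, an odds ratio below 1, was met, but it was the wrong outcome to name, because a single linked variant in nkat-3 need not move its neighbours. Linkage of nkat-3 was therefore left open. For haf-6, 0 of 2 mutated genes, rhy-1 and hif-1, lie on its chromosome, so linkage to a mutated gene was excluded, and an unlinked variant shared by the strains was not tested.

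The fall of sperm genes in egl-9;vhl-1 was weighed against less sperm in the worms and against 1 outlying library. The log2 fold changes of the 44 sperm genes had an SD of 0.40 around a median of −1.13, and 43 of them were below 0, which is consistent with less sperm tissue in the library. Regulation of the set by a common factor would also give a common ratio, and reads shared between near-identical major sperm protein genes would narrow the SD, so the cause was left open. In the lowest case, without N2 replicate 3, 35 sperm genes were called down against 40 with all libraries, which excluded 1 outlying library. Whether fewer sperm were made or more were used could not be told from RNA. A difference in the stage of the worms, weighed above for collagens, was not tested for the sperm genes and was left open too.

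Transcripts that matched no gene of the reference annotation were not analysed further. They held 0.125% of the counts of egl-9 replicate 1 and 0.127% of those of rhy-1 replicate 1, above the highest N2 library at 0.121%.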

How the results depend on the processing

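Every alternative was chosen before the data were examined, and none was added later. A number of genes was counted as changed when it moved by more than 1.5-fold, and a slope when it left its bootstrap interval. For every change given here the cause was not tested, except that fitting fewer libraries or testing transcripts leaves less evidence per test by construction.

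A fit of only the genotypes compared called 2234 for egl-9 against N2, 1014 for vhl-1 against N2, 1104 for hif-1 against N2, 283 for egl-9 hif-1 against N2 and 522 for egl-9;vhl-1 against egl-9. It gave 742 for egl-9 against vhl-1, 520 for rhy-1 against egl-9, 722 for the interaction of egl-9 and vhl-1, 514 for the shared response and 1118 for genes called back by hif-1 loss. The test of transcripts 1 by 1 gave 2210 for egl-9 against N2, 2518 for rhy-1 against N2, 790 for vhl-1 against N2, 591 for hif-1 against N2 and 413 for egl-9 hif-1 against N2. It gave 2312 for egl-9 hif-1 against hif-1, 229 for egl-9;vhl-1 against egl-9, 799 for egl-9 against vhl-1, 395 for rhy-1 against egl-9 and 495 for the interaction of egl-9 and vhl-1. It gave 428 for the shared response, 16 for the opposite response and 1365 for genes called back by hif-1 loss. A call at an adjusted p below 0.10 gave 2906 for hif-1 against N2, 1368 for egl-9 hif-1 against N2, 1698 for egl-9;vhl-1 against egl-9 and 48 for the opposite response. The slope for egl-9 and vhl-1 was −0.44 with only the genotypes compared, −0.624 with DESeq2, −0.588 at an adjusted p below 0.10 and −0.441 over genes also called in egl-9;vhl-1. The slope for egl-9 and hif-1 was −1.052 with the stricter filter, −0.961 with only the genotypes compared and −0.982 by ordinary least squares. RLE size factors and no filter moved none of these results.

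With each of the 21 libraries left out in turn, the number of genes ran from 940 to 1717 for vhl-1 against N2, from 835 to 2207 for hif-1 against N2, from 354 to 989 for egl-9 hif-1 against N2 and from 222 to 1789 for egl-9;vhl-1 against egl-9. It ran from 612 to 992 for rhy-1 against egl-9, from 645 to 1477 for the interaction of egl-9 and vhl-1, from 510 to 961 for the shared response and from 19 to 35 for the opposite response. The slopes ran from −0.628 to −0.436 for vhl-1 and from −1.043 to −0.94 for hif-1. The 469 genes changed in egl-9 and still called in egl-9 hif-1 fell to 194 without N2 replicate 2, and some numbers of list members called moved too. In the other comparisons and interactions, and in the number called back by hif-1 loss, no left-out library moved the number of genes by more than 1.5-fold.

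Camera with a preset correlation called 81 of the 200 list tests that were not called with the estimated correlation, and all called tests stayed called. The values that follow are adjusted p-values. For egl-9 against N2 this gave 0.0299 for the TCA cycle, 4.87e-04 for glycolysis, 0.00164 for the respiratory chain, 3.32e-07 for ribosomal proteins and 1.29e-05 for the proteasome. It also gave 0.0057 for heat shock genes, 0.00554 for detoxification, 8.84e-11 for collagens, 0.00729 for collagen folding, 1.53e-04 for yolk proteins, 3.01e-04 for sperm genes and 5.10e-05 for L4 molt genes. For rhy-1 against N2 this gave 0.00121 for the TCA cycle, 3.35e-09 for the respiratory chain, 2.82e-22 for ribosomal proteins, 5.03e-11 for the proteasome and 7.42e-04 for heat shock genes. Further values were 1.32e-04 for innate immunity, 5.03e-11 for collagens, 2.70e-05 for L4 molt genes and 0.00651 for male-enriched genes. For vhl-1 against N2 this gave 0.00421 for glycolysis, 6.51e-07 for the respiratory chain, 2.51e-07 for ribosomal proteins, 9.42e-05 for the proteasome and 5.64e-06 for heat shock genes. Other values were 0.00631 for detoxification, 0.00216 for the insulin pathway, 2.01e-05 for collagens, 0.00286 for yolk proteins and 0.0186 for oocyte genes. For hif-1 against N2 this gave 0.0166 for the hif-1 pathway, 0.00823 for hif-1 targets, 0.0198 for ribosomal proteins, 5.76e-07 for the proteasome and 1.42e-06 for heat shock genes. It also gave 1.30e-05 for detoxification, 1.30e-05 for collagens, 3.27e-06 for oocyte genes, 1.43e-05 for sperm genes and 3.11e-04 for intestinal genes. For egl-9 hif-1 against N2 this gave 0.028 for the hif-1 pathway, 0.0406 for iron homeostasis, 0.00145 for the TCA cycle, 0.0472 for glycolysis and 4.80e-05 for the respiratory chain. Further values were 6.30e-17 for ribosomal proteins, 0.00672 for yolk proteins, 2.70e-06 for oocyte genes, 0.028 for embryo genes, 6.04e-04 for muscle and 0.0406 for intestinal genes. For egl-9;vhl-1 against N2 this gave 1.99e-07 for glycolysis, 5.14e-10 for ribosomal proteins, 0.00259 for the proteasome, 0.00259 for detoxification and 0.0216 for lipid metabolism. Other values were 8.87e-04 for collagens, 0.0166 for collagen folding, 0.00235 for oocyte genes and 1.28e-13 for sperm genes. The interaction of egl-9 and hif-1 gave 1.42e-05 for glycolysis, 2.37e-09 for the proteasome, 1.87e-07 for heat shock genes, 6.90e-04 for the insulin pathway and 3.29e-04 for lipid metabolism. It also gave 3.20e-16 for collagens, 4.87e-05 for yolk proteins, 5.26e-06 for oocyte genes, 7.03e-05 for L4 molt genes and 0.0449 for intestinal genes. The interaction of egl-9 and vhl-1 gave 7.61e-04 for the TCA cycle, 2.44e-08 for the respiratory chain, 0.0133 for ribosomal proteins, 6.07e-06 for the proteasome and 9.41e-07 for heat shock genes. Further values were 0.00194 for the insulin pathway, 2.42e-14 for collagens, 4.97e-07 for yolk proteins, 3.73e-04 for sperm genes and 5.85e-05 for L4 molt genes.

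Among list tests, leaving out the filter ended the calls of the hif-1 pathway (0.0545) and male-enriched genes (0.189) in egl-9 against N2, the hif-1 pathway (0.151) in rhy-1 against N2 and the hif-1 pathway (0.158) and sulfide metabolism (0.0892) in vhl-1 against N2. It did so too for iron homeostasis (0.257) in hif-1 against N2 and the hif-1 pathway (0.0862), sulfide metabolism (0.0862) and male-enriched genes (0.0887) in egl-9;vhl-1 against N2. The same held for the hif-1 pathway (0.131) in the interaction of egl-9 and hif-1 and the hif-1 pathway (0.124) in the interaction of egl-9 and vhl-1. It called the insulin pathway (0.0415) in vhl-1 against N2, the insulin pathway (0.025) in the interaction of egl-9 and hif-1 and the insulin pathway (0.0378) in the interaction of egl-9 and vhl-1. The stricter filter called innate immunity (0.0336) in rhy-1 against N2, the insulin pathway (0.0223) in vhl-1 against N2, the insulin pathway (0.0359) in the interaction of egl-9 and hif-1 and the insulin pathway (0.0285) in the interaction of egl-9 and vhl-1. RLE size factors ended the call of iron homeostasis (0.067) in hif-1 against N2, and these called the insulin pathway (0.0473) in vhl-1 against N2, the insulin pathway (0.0456) in the interaction of egl-9 and hif-1 and the insulin pathway (0.0492) in the interaction of egl-9 and vhl-1. Fitting only the genotypes compared ended the calls of the hif-1 pathway (0.0748) and the insulin pathway (0.0702) in egl-9 against N2, the hif-1 pathway (0.408) and lipid metabolism (0.182) in rhy-1 against N2 and the hif-1 pathway (0.148), sulfide metabolism (0.148) and lipid metabolism (0.148) in vhl-1 against N2. It did so too for iron homeostasis (0.269) in hif-1 against N2, the insulin pathway (0.12) in egl-9;vhl-1 against N2 and the hif-1 pathway (0.116) in the interaction of egl-9 and vhl-1. It called the insulin pathway (0.0216), lipid metabolism (0.0233) and collagens (0.0233) in the interaction of egl-9 and hif-1.

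Leaving out single libraries changed the call of 18 list tests, and the ranges of their camera adjusted p follow. It ran from 0.045 to 0.273 for collagens and 0.0197 to 0.0788 for male-enriched genes in egl-9 against N2. The range was from 0.0296 to 0.112 for innate immunity, 0.0139 to 0.0502 for lipid metabolism and 0.0361 to 0.0862 for male-enriched genes in rhy-1 against N2. It went from 0.0154 to 0.133 for the insulin pathway in vhl-1 against N2. It ran from 0.0295 to 0.161 for hif-1 targets, 0.0057 to 0.161 for iron homeostasis, 0.0395 to 0.479 for heat shock genes and 0.0495 to 0.212 for detoxification in hif-1 against N2. The range was from 0.0381 to 0.106 for glycolysis in egl-9;vhl-1 against N2. It went from 0.0389 to 0.241 for heat shock genes, 0.0194 to 0.0957 for the insulin pathway, 0.0389 to 0.121 for lipid metabolism and 0.025 to 0.172 for collagens in the interaction of egl-9 and hif-1. It ran from 0.0325 to 0.134 for the hif-1 pathway, 0.0386 to 0.283 for heat shock genes and 0.0203 to 0.137 for the insulin pathway in the interaction of egl-9 and vhl-1. Of 4200 such values 33 lost and 42 gained a call.

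Replicate numbers carry no stated meaning. Over 63 pairs of libraries with the same number in different genotypes, the median correlation of what genotype left unexplained was 0.014 (−0.29 to 0.253). These correlations were also averaged over the libraries of other genotypes with each number. By that mean, 11 of 21 libraries correlated best with their own number. With the replicate number as a block (replicate block), the slope for egl-9 and vhl-1 was −0.468 and the calls of male-enriched genes (0.0554) in egl-9 against N2, iron homeostasis (0.11) in hif-1 against N2 and the hif-1 pathway (0.0727) in the interaction of egl-9 and vhl-1 were lost.

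For the 828 values of named genes, 22970 of 23970 recomputed values kept their call and direction, 976 lost the call, 15 gained it and 9 reversed. Lost calls numbered 175 by transcripts, 106 with only the genotypes compared, 31 without the filter, 16 with the replicate block, 9 with RLE size factors, 1 with the stricter filter, 1 with DESeq2 and 637 over the fits with 1 library left out. By transcripts egl-9 in hif-1 against N2 was at −3.25, egl-9 in egl-9 hif-1 against N2 was at −1.28 and ric-7 in rhy-1 against N2 was at −0.26, each without a call. The vhl-1 transcript, which has few counts and was not called where the gene is intact, ran over the left-out libraries from −0.11 to 0.36 in egl-9, from −0.66 to 0.01 in rhy-1, from −0.15 to 0.32 in hif-1 and from −0.15 to 0.32 in egl-9 hif-1, and so crossed 0. Of 5387 recomputed list values 5193 kept their call, and 95 of these, called in neither setting, pointed the other way. The stricter filter gave a value for 192 of 200 list tests and 799 of 828 gene values, and fits of only the genotypes compared for 195 and 821, because genes or members fell below the filter there. Transcripts gave 827 and DESeq2 823 of the gene values.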

Other observations

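The single test in this part, on genes that changed in opposite directions, was written before the data were examined, and nothing here was chosen after the results were seen except which genes to describe.

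Heat shock genes differed widely between the libraries of N2, egl-9 and rhy-1 and less between those of the other genotypes. In N2, egl-9, rhy-1 and vhl-1 their level rose in the order of the replicate numbers. It rose slightly in egl-9 hif-1 too, while in hif-1 it fell and in egl-9;vhl-1 replicate 3 was the lowest. The level of the 16 measured heat shock genes and chaperones, relative to the N2 mean, was −1.87, 0.76 and 1.11 in the 3 N2 libraries, −1.64, −0.75 and −0.21 in egl-9, −2.29, −0.65 and 0.38 in rhy-1, −2.17, −1.95 and −1.19 in vhl-1, −0.73, −0.72 and −0.98 in egl-9;vhl-1, −2.32, −2.53 and −2.55 in hif-1 and 0.34, 0.36 and 0.47 in egl-9 hif-1. The inducible chaperone gene hsp-70 was at 1.964, 125.9 and 138.5 CPM in the N2 libraries and at 0.653 ± 0.503 in hif-1, with a log2 fold change of −6.98 (edgeR adjusted p = 0.0135), and the call was lost without hif-1 replicate 2 (0.0531) or hif-1 replicate 3 (0.0636) and with only hif-1 and N2 fitted (0.125). The list was not called by camera in hif-1 (adjusted p = 0.336), but it was without N2 replicate 1 (0.0395), the N2 library with the low level. In the interaction of egl-9 and hif-1, 12 of 16 members were called up and 1 down (13 and 1 adjusted over the list alone, camera adjusted p = 0.194, or 0.0389 without N2 replicate 1). A brief warming or other stress of some plates could raise these genes. The camera adjusted p in hif-1 moved from 0.336 to 0.0395 with the removal of N2 replicate 1, so the list call depends on that library. Replicate 1 was also the lowest in egl-9, rhy-1 and vhl-1, so N2 replicate 1 need not be a lone outlier. With the replicate number as a block, no camera test of this list gained or lost a call. The effect of the replicate number itself on these genes was not tested. The cause was not tested.

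Among the 29 genes called in opposite directions in egl-9 and vhl-1, 18 were also called in hif-1, and 7 of these 18 moved as in egl-9. The idea that the egl-9 direction is that of hif-1 loss was neither met nor excluded by this count. The iron genes ftn-1, ftn-2 and smf-3 were among the 7, while asp-8, nlp-31 and F55G11.2 were among those that moved the other way in hif-1. The ferritin gene ftn-1, which stores iron and is repressed when iron is scarce, was higher in egl-9, hif-1, egl-9 hif-1 and egl-9;vhl-1 (266 ± 28.4, 91.0 ± 20.9, 68.1 ± 6.55 and 199 ± 26.6 CPM) than in N2 (2.67 ± 1.39), and was low in vhl-1 (0.336 ± 0.107) and near N2 in rhy-1 (4.44 ± 1.48). The importer gene smf-3 showed the reverse, with 40.4 ± 9.32 CPM in vhl-1, 1.97 ± 0.0840 in N2, 0.248 in hif-1, 0.148 in egl-9;vhl-1, 0.071 in egl-9 hif-1 and 0 in egl-9, and with 2.812 in rhy-1, where it was not called (edgeR adjusted p = 0.364).

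Lists of embryonic, muscle and collagen folding genes were not called by camera with the estimated correlation in the 6 comparisons with N2. Their adjusted p-values ran from 0.386 to 0.906, from 0.386 to 0.922 and from 0.308 to 0.989. With the preset correlation camera called embryonic (0.028) and muscle genes (6.04e-04) in egl-9 hif-1 and collagen folding genes in egl-9 (0.00729) and egl-9;vhl-1 (0.0166). Members were called as well, with 9 of 24 muscle genes down and none up in egl-9 hif-1, a number that was 3 without N2 replicate 2 and 4 without egl-9 hif-1 replicate 3, and 2 with only egl-9 hif-1 and N2 fitted. The male-enriched list was also not called in hif-1 (0.73) or egl-9 hif-1 (0.989).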
